A study of Mus musculus with 4 samples.

How the data were processed

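RNA of endothelial cells from mouse spleen was measured on 1-colour Agilent arrays. The mice were heterozygous for a reporter that places green fluorescent protein (GFP) at the Ackr4 locus. Per the labels, spleens were digested at 37 °C for 45 and then 20 minutes, red cells were lysed, and CD45-bearing cells were depleted with beads. Living single cells without CD45 and with the endothelial surface protein CD31 were then sorted by GFP into ACKR4-positive and ACKR4-negative cells. Cells of 2 to 3 mice were pooled in each of 2 independent sorts, which gave 4 arrays, 2 per group. Between 6 and 20 ng of RNA was amplified and labelled. The file headers place all 4 arrays on 1 slide and in 1 scan.

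Spot signals were made by the authors with Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed signal is an intensity, background-subtracted and detrended within each array, with low values replaced by surrogates, and it was not scaled between arrays. The deposited table of processed intensities is on a linear scale with each array's 75th percentile set to 1500 and a lowest value of 15. This was checked against the scanner files, where log2 values correlated at 1.00 on all 4 arrays, and 32.4% to 34.5% of its values sat at 15. The comparisons used the scanner files, and the table served as an alternative.

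Each array held 162570 spots, of which 157716 carried 39429 non-control probes with 4 spots each. Spots marked as non-uniform or as population outliers, 1.91% to 1.96% per array, were left out. The other spots of a probe were averaged as log2 signal, and the array's 75th percentile over non-control probes was subtracted, so a level of 0 equals that percentile. A probe was tested when over 50% of its spots were well above background on both arrays of at least 1 group. Where a gene had several tested probes, the brightest stood for it. Probes were named through a RefSeq list of mouse genes, with 27508 matched by accession, 3544 carrying a current symbol, 167 matched through another probe of the gene, and 8210 keeping the name in the file. Coordinates are the probe positions of the files, on mm9.

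ACKR4-positive arrays were compared with ACKR4-negative arrays by limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Other versions were jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9. Errors given with log2 fold changes are standard errors of the fit, with n = 2 arrays per group, and positive values are higher in ACKR4-positive cells. Where a gene was well above background on neither array of its dimmer group, the fold is also given as a lower bound. Lrrc25, Alcam, Sema3g, Unc5b, Rgcc, Mmrn1, Epor, Smad6 and Nfe2 were so on 1 of these 2 arrays and have no bound. For that bound, levels of the dimmer group were raised to the lowest level well above background on their array.

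Gene lists were fixed before the data were examined, 38 in all, of which 15 held cell type markers and 23 held functional groups. Lists with at least 5 tested members, 37 of them, were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 37 lists. With a correlation estimated from these arrays, 0 of the 37 lists passed, and the lowest adjusted p was 0.317. In that setting each list's p rests on few residual degrees of freedom. The camera fit on ranks called 12 lists. The fry test, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, called 16. Across all lists, 6 entries had no probe.

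Named genes were chosen by a rule written before the data were examined. It takes Ackr4, the 10 largest rises and 10 largest falls among called genes that differ in the same direction in both sorts and are well above background on both arrays of the higher group, and up to 4 members per list with the smallest p. Predicted and clone-type names were left out. Some genes that the rule takes are not reported here. Genes named outside this rule complete a count of 5 or fewer or are singled out as such. They were chosen after their values were seen and are Jag1, Dll1, Meox1, Eln, Col5a2, Vldlr, Fzd9, Thbd, Trpv4, Esam, Pecam1, Cdh5, Epha7, Sema3c, Sema3a, Plxnb1 and most genes of the closing section.

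Alternatives covered background correction by normexp with an offset of 50, quantile normalization, median centring, no filter and a stricter filter on dim probes, the floor of 15, and the values the authors deposited. They also covered the mean of a gene's probes, probes in place of genes, spots marked as outliers kept, a trended prior, a 2-fold minimum, an adjusted p under 0.1, other list tests, sort number as a replicate block, and leaving out each array in turn. A slide block was not run because there was 1 slide. The sort number is the replicate number of the labels, read as the sort because the titles give both arrays of a replicate the same mouse number and the design names 2 sorts. It pairs 1 array of each group, and every value per sort or with the replicate block rests on this reading. Across genes, which are not independent replicates, the difference between sorts correlated between the groups at r = 0.605 (Spearman rho = 0.631), and the second principal component, 27.8% of the variance, separated the sorts.

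The procedure was tested on simulated data for this comparison, with 17362 genes, 200 of them changed, in each of 5 runs. Of 250 changed genes per size, it recovered 0% at 2-fold, 0% at 4-fold, 43.6% at 16-fold and 78.4% at 256-fold. False calls made up 2.56% of its calls, and 5.79% of unchanged genes had an unadjusted p under 0.05. It called 5 of 5 lists shifted by a log2 of 1 and 0 of 500 lists without a shift. Simulated genes varied independently of each other and the lists were random. These list counts therefore do not show how often lists of genes that vary together are called falsely. In the data the estimated correlation between genes of a list reached 0.957, for ribosomal protein genes. At first 80% recovery was asked for at 256-fold. After that was missed, this bar was dropped and replaced by bars on false calls, mean error and shifted lists, which were met. In this unpaired fit, simulated changes of 4-fold or less were out of reach, and the number of arrays limits the precision. The simulation changed 200 genes per run, whereas 976 were called in the data. Some of these lay below 4-fold, such as Cspg4 at a log2 fold change of -1.71. With sort number as a replicate block 2656 genes were called, so the limit belongs to the fit and the simulation as well as to the arrays.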

Results

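The data were genome-wide expression levels of splenic endothelial cells sorted by an Ackr4 reporter, with 2 arrays of ACKR4-positive and 2 arrays of ACKR4-negative cells from 2 independent sorts. Signal was well above background for 21972 and 22365 probes on the ACKR4-negative arrays and for 22976 and 21663 probes on the ACKR4-positive arrays, 54.9% to 58.3% of 39429 probes. The 75th percentile of the signal was 767 and 656 in ACKR4-negative and 950 and 589 in ACKR4-positive replicates 1 and 2. Levels correlated between arrays at 0.972 within the ACKR4-negative group, 0.961 within the ACKR4-positive group and 0.902 to 0.934 between groups. The first principal component, 66.1% of the variance, separated the groups. The median signal of spiked-in control RNA was 847 on ACKR4-negative replicate 1 against 2805 to 3432 on the other 3 arrays.

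The comparison asked how the expression of CD31-positive spleen cells that carry the ACKR4 reporter differs from that of CD31-positive cells that lack it. ACKR4-positive cells had much lower signal of arterial genes such as Sox17 and Dll4, of capillary genes such as Gpihbp1, and of the VEGF-responsive genes Esm1 and Aplnr. They had higher signal of Clec4g, a lectin of sinusoidal endothelium, of the ligand Wnt9b, and of the atypical chemokine receptor Ackr2. Sinusoidal genes as a list were not called (adjusted p = 0.268), with 9 of 19 members higher and 7 lower in both sorts. Both groups carried signal of Pecam1, which encodes CD31, and of Cdh5, the endothelial cadherin, with log2 fold changes of -0.15 ± 0.41 and -0.69 ± 0.33, which were not called. Differences of this size are below the 2-fold changes that the procedure did not recover in simulated data. These 2 genes were chosen from the pan-endothelial list after their values were seen. That list was called downward with 7 of 28 members fallen (adjusted p = 8.70e-04, and adjusted p = 0.402 with an estimated correlation). Of 27 arterial genes 17 were called lower in ACKR4-positive cells, of 18 capillary genes 8, of 18 megakaryocyte and platelet genes 15, and of 15 mural genes 4. Called or not, 24, 13, 17 and 14 members of these lists were lower in both sorts. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.317 for arterial genes and 0.402 for the others). The estimates were -0.028 for arterial, 0.082 for capillary, 0.311 for megakaryocyte and platelet and 0.015 for mural genes, against the preset 0.01. That setting also left few residual degrees of freedom.

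Ackr4, whose locus drove the sorting reporter, rose by a log2 fold change of 8.69 ± 0.95 (adjusted p = 0.0181), with a higher level in both sorts. Its probe lies on chromosome 9 at 104000864 to 104000923 (mm9). Its levels were -7.53 and -7.50 in ACKR4-negative and -0.21 and 2.55 in ACKR4-positive cells, a difference of at least 6.75 on the log2 scale. Because the cells were chosen by this locus, the value checks the labels and is no finding.

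Of 17362 tested genes, 976 differed (5.62%), of which 332 rose and 644 fell in ACKR4-positive cells. All 976 differed by at least 2-fold and in the same direction in both sorts, and 300 differed by at least 16-fold, with 52 risen and 248 fallen. With sort number as a replicate block, 2656 genes differed, 1172 risen and 1484 fallen, and the 976 were among them. At least 2-fold differences in both sorts were seen for 2180 genes, 890 higher and 1290 lower, against 1167 when arrays were paired within groups. The third pairing, 1843, again sets ACKR4-positive against ACKR4-negative arrays and is no value without a group difference. Across genes, which are not independent replicates, the differences of the 2 sorts correlated at r = 0.817 (Spearman rho = 0.658), and 73.1% had the same sign. Without ACKR4-negative replicate 1, the array with the weak spike-in signal, 387 genes differed, 75 risen and 312 fallen. Leaving out ACKR4-negative replicate 2 gave 448 genes and leaving out ACKR4-positive replicate 1 gave 511.

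**Figure D1:**
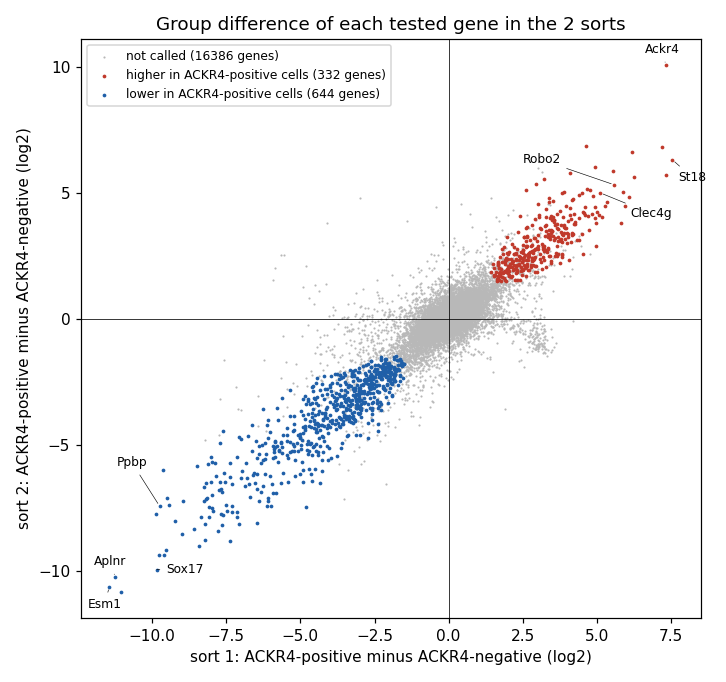
Log2 difference between ACKR4-positive and ACKR4-negative cells in sort 1 (horizontal) and sort 2 (vertical), 1 point per tested gene. The 332 risen genes (red) lie above 0 in both sorts and the 644 fallen genes (blue) lie below 0 in both.

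After Ackr4, the largest rises in log2 fold change were those of St18, a zinc finger transcription factor, at 6.92 ± 0.41 (adjusted p = 0.00776, at least 117-fold, chromosome 1 at 6850155 to 6850214, mm9) and of Lrrc25 at 6.51 ± 0.76, whose probe was not well above background on ACKR4-negative replicate 1. Lama1, a laminin alpha chain of basement membranes, rose by 6.40 ± 0.80 (at least 46.7-fold), and the lipase gene Lipn by 5.93 ± 0.58. Robo2, a receptor for Slit guidance proteins, rose by 5.45 ± 0.27 (adjusted p = 0.00686, at least 12.5-fold, chromosome 16 at 73894653 to 73894712, mm9). Gprin1, Apol7b, Pcdh9 and Adgrb2 rose by 5.73 (at least 20.3-fold), 5.69, 5.48 (at least 32.1-fold) and 5.45. The calls of Lama1 and Lrrc25 were lost without ACKR4-positive replicate 1 (adjusted p = 0.0558 and 0.0511), and that of Apol7b without ACKR4-negative replicate 1 (adjusted p = 0.0510).

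The largest fall in measured signal, where others are limited by background, was that of Esm1, a secreted proteoglycan of angiogenic endothelium, at -11.05 ± 0.49 (adjusted p = 0.00638, chromosome 13 at 114008204 to 114008263, mm9). Its levels were 7.39 and 7.78 in ACKR4-negative and -4.06 and -2.86 in ACKR4-positive cells. Sema7a, a membrane-anchored semaphorin, fell by 10.95 ± 0.37 (at least 603-fold). The apelin receptor gene Aplnr had a log2 fold change of -10.76 ± 0.49 (at least 1104-fold) and Sox17, a transcription factor of arterial endothelium, of -9.90 ± 0.34 (at least 886-fold). Btnl9 stood at -9.58 ± 0.28 (at least 665-fold), Sema3g at -8.81 ± 0.73, Tmem178 at -8.78 ± 0.33 (at least 127-fold), and the retinol-binding protein gene Rbp7 at -8.73 ± 0.54 (at least 118-fold). Ppbp, a platelet chemokine, fell by 8.59 ± 1.37 (adjusted p = 0.0429), a call that was lost without ACKR4-negative replicate 1 or 2 (adjusted p up to 0.0854). With the stricter filter on dim probes, Btnl9 was read from another probe at -0.75 (adjusted p = 0.427) and Ppbp had an adjusted p of 0.0541.

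**Figure D2:**
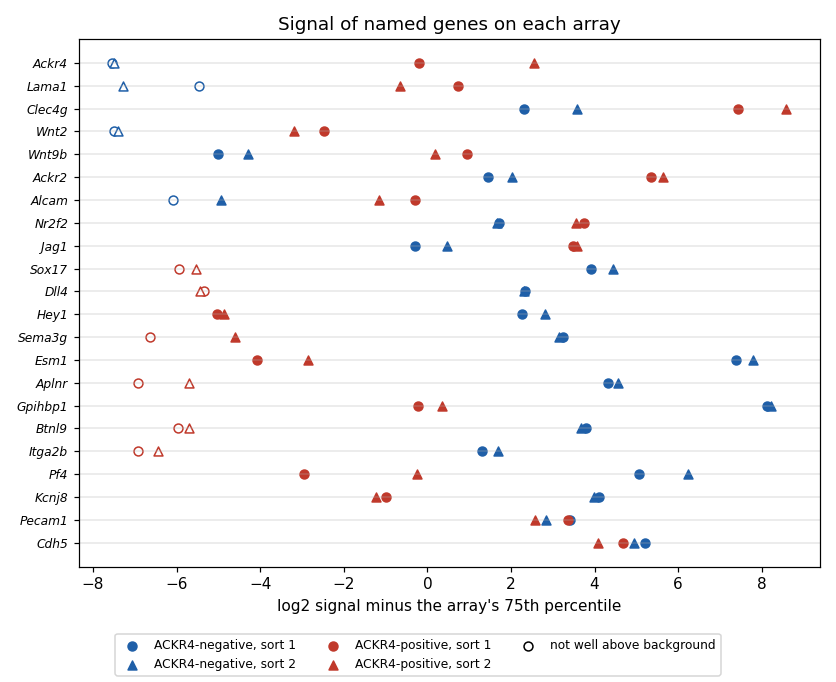
Log2 level of named genes on each of the 4 arrays, relative to the array's 75th percentile, in ACKR4-negative (blue) and ACKR4-positive (red) cells, with open symbols where the probe was not well above background. Sox17, Dll4 and Aplnr are not well above background in either ACKR4-positive replicate, nor Ackr4 in either ACKR4-negative replicate, and Pecam1 lies at 2.58 to 3.41 on all 4.

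Of 27 tested arterial genes, 17 fell, 1 rose and 9 were not called, and adjusted over the list alone 23 fell and 1 rose. The median log2 fold change was -4.63 (-3.91 with members dim in 1 group at their bound; adjusted p = 4.60e-20, and adjusted p = 0.317 with an estimated correlation). Besides Sox17, they included Dll4, a Notch ligand, at -7.71 ± 0.26 (at least 200-fold), Unc5b, a netrin receptor, at -8.49 ± 0.36, the Notch target gene Hey1 at -7.48 ± 0.32, and the arterial connexin gene Gja5 at -8.09 ± 0.60 (at least 106-fold). The member that rose was Jag1, another Notch ligand, at 3.44 ± 0.36. For Gja5, the stricter filter on dim probes took another probe, which gave 0.17 and an adjusted p of 0.875.

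Capillary genes fell in 8 of 18 tested members, 1 rose and 9 were not called, and adjusted over the list alone 8 fell and 2 rose. Their median was -1.42 (-1.31 at the bound; adjusted p = 4.33e-05, and adjusted p = 0.402 with an estimated correlation). Gpihbp1, which anchors lipoprotein lipase on capillary endothelium, fell by 8.11 ± 0.32, the water channel gene Aqp1 stood at -7.28 ± 0.35 and Rgcc at -5.42 ± 0.58, while Meox1 rose by 2.84 ± 0.36. Pan-endothelial genes fell in 7 of 28, with a median of -0.58 (8 adjusted over the list alone; adjusted p = 8.70e-04, and adjusted p = 0.402 with an estimated correlation). These 7 included Vwf, the von Willebrand factor gene, at -6.61 ± 0.41, and the adhesion receptor gene Adgrl4 at -3.69 ± 0.49. The Adgrl4 call was lost without ACKR4-negative replicate 1 or 2, with values of -3.54 and -3.84. Megakaryocyte and platelet genes fell too, and a share of platelet RNA in these 7 falls was not tested.

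Sinusoidal endothelial genes were not called as a list (adjusted p = 0.268), though fry called them upward (adjusted p = 0.0359), with 3 risen, 1 fallen and 15 not called, and 6 risen and 3 fallen adjusted over the list alone. Clec4g rose by 5.05 ± 0.63, from levels of 2.31 and 3.59 to 7.43 and 8.57. Wnt2, a Wnt ligand made by liver sinusoidal endothelium, rose by 4.61 ± 0.35 (at least 6.71-fold), and Cd55, a complement regulator, by 2.89 ± 0.30. Adam23 fell by 3.66 ± 0.42 (at least 3.62-fold). Venous genes (adjusted p = 0.184, and 0.0256 with fry) held 1 rise, that of Nr2f2, a transcription factor of venous identity, at 1.96 ± 0.27, and 3 falls, those of Vwf, Cpe at -3.86 ± 0.29 and the P-selectin gene Selp at -3.36 ± 0.32, and adjusted over the list alone 2 rose and 5 fell. Neither list was called with an estimated correlation (adjusted p = 0.563 for both). The Nr2f2 call was lost without any 1 of the 4 arrays, while its log2 fold change stayed at 1.87 to 2.05. Fits with 1 array fewer have less precision, so a lost call in them need not mean a moved value. The calls of Cd55, Adam23 and Selp were lost without ACKR4-negative replicate 1 or 2 (adjusted p up to 0.0735, 0.0682 and 0.0562), that of Cd55 also without ACKR4-positive replicate 1. Normexp background correction took Wnt2 to 1.36 (adjusted p = 0.0568) and Adam23 to -0.94 (adjusted p = 0.258).

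Marginal sinus and high endothelial genes held 1 rise, that of Ackr4 itself, and 2 falls among 9 members, with an adjusted p of 0.0596 (1 rose and 3 fell adjusted over the list alone). Without Ackr4, the sorting gene, the list was called downward (median -1.78, adjusted p = 0.00534), and it was called in 7 of 19 alternatives, among them the stricter filter (adjusted p = 0.00182) and the replicate block (adjusted p = 0.0220). It was not called with an estimated correlation (adjusted p = 0.416). The replicate block also called Fut7 of this list (adjusted p = 0.00400). The falls were those of Enpp2, the autotaxin gene, at -7.75 ± 0.63 and of Cd34 at -2.25 ± 0.30. Lymphatic genes (adjusted p = 0.340) held 1 rise, that of Sema3d at 4.38 ± 0.59, and 1 fall, that of Mmrn1 at -5.71 ± 0.46, among 11 members, and adjusted over the list alone 2 rose and 3 fell. Mmrn1, like Selp above, is also in the megakaryocyte and platelet list, which fell. The replicate block called Nts and Thy1 of the lymphatic list (adjusted p = 0.00217 and 0.00925). Sema3d was lost without ACKR4-negative replicate 2 or ACKR4-positive replicate 1 (adjusted p up to 0.0690), and Cd34 without any 1 of the 4 arrays (adjusted p = 0.0802 to 0.149).

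Markers of cell types other than endothelium also differed. Megakaryocyte and platelet genes fell in 15 of 18 members (17 adjusted over the list alone) with a median of -6.12 (-5.74 at the bound; adjusted p = 1.71e-18, and adjusted p = 0.402 with an estimated correlation). Itga2b, a platelet integrin chain, fell by 8.18 ± 0.33 (at least 143-fold), and Gp5, Tubb1 and Clec1b had values of -7.50 ± 0.41 (at least 87.5-fold), -7.26 ± 0.39 (at least 54.5-fold) and -6.54 ± 0.33. Mural and smooth muscle genes fell in 4 of 15 members (12 adjusted over the list alone) with a median of -3.72 (-3.57 at the bound; adjusted p = 1.67e-08, and adjusted p = 0.402 with an estimated correlation). The 4 were the potassium channel genes Kcnj8 and Abcc9 of pericytes, at -5.16 ± 0.27 and -4.69 ± 0.43, Myh11 at -3.72 ± 0.49 (at least 4.99-fold) and Cspg4 at -1.71 ± 0.28. Myh11 was lost without ACKR4-negative replicate 1 or ACKR4-positive replicate 1 (adjusted p up to 0.0732) and Cspg4 without any 1 of the 4 arrays (adjusted p = 0.133 to 0.292). With normexp, Myh11 stood at -1.04 (adjusted p = 0.236) and Cspg4 at -1.10 (adjusted p = 0.112). Cspg4 also lost its call with median centring, without a filter, with the stricter filter and with the trended prior (adjusted p = 0.0528 to 0.0721).

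Erythroid genes fell in 3 of 11 members, also adjusted over the list alone, with a median of -1.97 (-1.92 at the bound; adjusted p = 0.00929, and adjusted p = 0.563 with an estimated correlation). Gata1, a transcription factor of red cell and megakaryocyte precursors, fell by 7.28 ± 0.51 (at least 81.2-fold), and Car2 and Epor had values of -6.04 ± 0.84 and -4.17 ± 0.27. The list's median was -4.53 in sort 1 and 0.60 in sort 2, and without ACKR4-negative replicate 1 it was 0.35 (adjusted p = 0.296). The Car2 call was lost without ACKR4-positive replicate 1 (adjusted p = 0.0822). Tfrc was called with the replicate block (adjusted p = 0.00798). Fibroblastic reticular genes had a median of -0.67 with 0 of 17 members called and 5 fallen adjusted over the list alone (adjusted p = 0.00514, and adjusted p = 0.619 with an estimated correlation). Without ACKR4-negative replicate 2 the adjusted p of that list was 0.250. Its members with the smallest p, Cxcl13, Pdgfrb, Tcf21 and Lepr, had log2 fold changes of -3.15 to -1.74, and the replicate block called all 4 (adjusted p = 0.00265 to 0.0192).

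Leukocyte lists were not called. Macrophage genes (adjusted p = 0.316, 0.0443 with the replicate block, and 0.0287 without ACKR4-negative replicate 1) held 2 rises, among them that of the iron exporter gene Slc40a1 at 1.89 ± 0.32, and a fall of Hmox1 at -2.58 ± 0.41, with 2 risen and 2 fallen adjusted over the list alone. With the replicate block Marco was called (adjusted p = 0.0124). Slc40a1 and Lck lost their calls without any 1 of the 4 arrays and Hmox1 in all of these fits but that without ACKR4-positive replicate 2 (adjusted p up to 0.263). All 3 also lost them with the stricter filter (adjusted p = 0.0529 to 0.0593), Slc40a1 and Lck without a filter (adjusted p = 0.0673 and 0.0584), and Slc40a1 with quantile normalization (adjusted p = 0.0566). Lymphocyte genes (adjusted p = 0.959) held 1 fall among 11 members, that of Lck at -2.002 ± 0.32, also adjusted over the list alone. Granulocyte and monocyte genes (adjusted p = 0.629) held 0 changes among 7 members, adjusted over the list alone as well, while the replicate block called Lyz2 and S100a9 (adjusted p = 0.0263 and 0.0248). Of the mesothelial genes, 3 were tested, 0 were called over all genes and 1 rose adjusted over the list alone (Msln, adjusted p = 0.0102 with the replicate block), and the list was not tested.

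**Figure D3:**
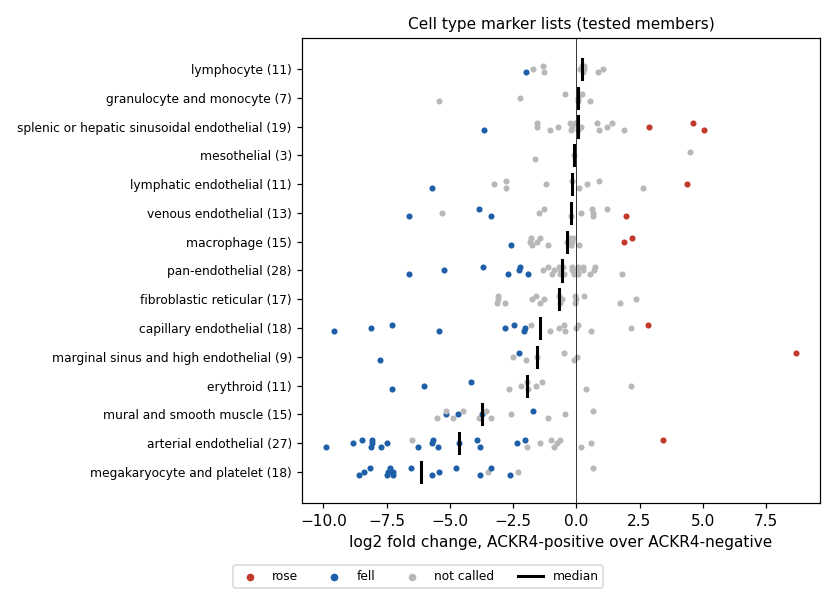
Log2 fold change of each tested member of the 15 cell type lists, ACKR4-positive over ACKR4-negative, with risen members in red, fallen members in blue, members not called in grey and the list median as a black bar. The medians of megakaryocyte and platelet genes (-6.12), arterial genes (-4.63) and mural genes (-3.72) lie farthest below 0.

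Notch pathway genes fell in 8 of 29 members and rose in 2, with a median of -0.49 (9 fell and 3 rose adjusted over the list alone; adjusted p = 0.00579, and adjusted p = 0.407 with an estimated correlation). Dll4, Hey1, Notch4 at -5.66 ± 0.44 and Hey2 at -5.48 ± 0.36 (at least 12.3-fold) were among the 8, while the ligand genes Dll1, at 3.63 ± 0.32, and Jag1 rose. These 4 falls are also in the arterial list. Of matched members, 22 of 27 arterial, 8 of 29 Notch, 13 of 28 VEGF, 8 of 45 guidance and 14 of 33 junction genes are in other lists too. The calls of these lists are therefore not separate results. VEGF and angiopoietin genes fell in 10 of 25 members and rose in 0, with a median of -0.12 and a mean of -2.25 (11 fell and 2 rose adjusted over the list alone; adjusted p = 0.00181, and adjusted p = 0.402 with an estimated correlation). Besides Esm1 and Aplnr they held Nrp1, a semaphorin and VEGF co-receptor gene, at -8.11 ± 0.58 (at least 148-fold), and Angpt2 at -7.10 ± 0.44 (at least 88.3-fold). Limited to probes well above background on all 4 arrays, the VEGF median was 0.07 (adjusted p = 0.575) and the Notch list was not called (adjusted p = 0.265).

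Guidance genes changed in both directions, with 10 of 38 members fallen, 6 risen and a median of -0.67 (15 fell and 7 rose adjusted over the list alone; adjusted p = 0.0110, and adjusted p = 0.619 with an estimated correlation). The falls included Sema7a, Sema3g, Unc5b and Nrp1. Besides Robo2 and Sema3d, the rises were those of Epha7 at 3.98, Sema3c at 3.75, Sema3a at 3.47 and Plxnb1 at 2.30. The list's call was kept in 13 of 19 alternatives. It was lost without ACKR4-negative replicate 1 (adjusted p = 0.0712) or ACKR4-positive replicate 2 (adjusted p = 0.190), with the stricter filter (adjusted p = 0.108), ranks (adjusted p = 0.0825) and fry (adjusted p = 0.0768).

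Basement membrane and matrix genes fell in 9 of 36 members and rose in 3, with a median of -0.84 (15 fell and 3 rose adjusted over the list alone; adjusted p = 4.33e-05, and adjusted p = 0.416 with an estimated correlation). Col18a1, a basement membrane collagen gene, had a value of -7.40 ± 0.49, Thbs1 of -5.96 ± 0.38, Lamb1 of -4.79 ± 0.33 (at least 11.4-fold) and Sparcl1 of -4.58 ± 0.37. The 3 rises were those of Lama1, the elastin gene Eln at 3.44 ± 0.34 and Col5a2 at 2.67 ± 0.36 (at least 5.05-fold). TGF-beta and BMP genes fell in 6 of 28 members and rose in 1, with a median of -0.80 (12 fell and 1 rose adjusted over the list alone; adjusted p = 3.53e-04, and adjusted p = 0.402 with an estimated correlation). Smad6, Ltbp1 and Inhbb had values of -5.59 ± 0.44, -5.48 ± 0.51 (at least 15.5-fold) and -4.91 ± 0.56, and Tgfb3 rose by 2.99 ± 0.40. Inhbb lost its call without ACKR4-negative replicate 2 (adjusted p = 0.0503), Tgfb3 in 3 of the 4 fits without 1 array (all but that without ACKR4-negative replicate 2, adjusted p up to 0.0944), and Lamb1 with normexp (-1.71, adjusted p = 0.0540).

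Chemokine receptor genes were the 1 list called upward, with 3 of 11 members risen and 1 fallen and a median of 0.36 (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0462, and adjusted p = 0.619 with an estimated correlation). Ackr4, the sorting gene, is among the 3. The others, the scavenging receptor genes Ackr2 and Ackr3, rose by 3.75 ± 0.34 and 2.04 ± 0.29, and Cxcr4 fell by 5.35 ± 0.64 (at least 14.9-fold). The list's call was kept in 7 of 19 alternatives. It was lost without Ackr4 (adjusted p = 0.164), with the replicate block (adjusted p = 0.0610), without a filter (adjusted p = 0.202), with quantile normalization, median centring, the floor of 15 and the authors' values (adjusted p = 0.0534 to 0.0746), and with ranks and fry (adjusted p = 0.126 and 0.215). It was also lost without ACKR4-negative replicate 1 (adjusted p = 0.116) and without ACKR4-positive replicate 2 (adjusted p = 0.199). Ackr3 lost its call without any 1 of the 4 arrays (adjusted p = 0.0702 to 0.180) and with quantile normalization (adjusted p = 0.0889), and Cxcr4 without ACKR4-negative replicate 2 (adjusted p = 0.0519).

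Chemokine ligand genes had a median of -0.78 (adjusted p = 0.0380, and adjusted p = 0.627 with an estimated correlation), with 2 of 19 fallen and 1 risen, and 6 fallen and 2 risen adjusted over the list alone. The 2 that fell, Ppbp and Pf4, at -7.24 ± 1.01, are platelet chemokines, and without the members of the megakaryocyte list the adjusted p was 0.189. Cxcl10, an interferon-induced chemokine, rose by 3.03 ± 0.33. The list's call was kept in 11 of 19 alternatives. It was lost without ACKR4-negative replicate 2 or ACKR4-positive replicate 1 (adjusted p = 0.0562 and 0.0591), with normexp (adjusted p = 0.0628), the stricter filter (adjusted p = 0.168), ranks (adjusted p = 0.0825) and fry (adjusted p = 0.430). Pf4 lost its call without ACKR4-negative replicate 2 (adjusted p = 0.0627), and Cxcl10 without either ACKR4-negative array (adjusted p up to 0.0775) and with the mean of its probes (2.30, adjusted p = 0.138).

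Cell junction and transport genes fell in 4 of 27 members, Cdh13 at -8.09 ± 0.57 (at least 84.9-fold), Gja5, Aqp1 and Esam, and rose in 1, Jam2 at 2.30 ± 0.26 (7 fell and 3 rose adjusted over the list alone). The median was -0.35 (adjusted p = 0.00967, and adjusted p = 0.402 with an estimated correlation). Lipid handling genes fell in 8 of 38 members, among them Gpihbp1, Enpp2, the scavenger receptor gene Scarb1 at -3.25 ± 0.28 and the sphingosine phosphate transporter gene Spns2 at -3.01 ± 0.34, and rose in 1, Vldlr at 2.42 ± 0.38 (at least 2.35-fold; 11 fell and 3 rose adjusted over the list alone). The median was -0.38 (adjusted p = 0.0111, and adjusted p = 0.402 with an estimated correlation), and the call was lost without ACKR4-positive replicate 2 (adjusted p = 0.0562). Without ACKR4-negative replicate 2, Scarb1 had an adjusted p of 0.0519, and Spns2 lost its call without either ACKR4-negative array (adjusted p up to 0.0848).

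Cell cycle genes had a median of -0.65 with 0 of 27 members called, also adjusted over the list alone (adjusted p = 5.38e-04, and adjusted p = 0.563 with an estimated correlation), and 19 of the 27 were lower in both sorts. The replicate block called Cdt1, E2f1 and Aurka (adjusted p = 0.0120 to 0.0280). Cytosolic ribosomal protein genes had a median of -0.38 with 0 of 43 called, also adjusted over the list alone (adjusted p = 0.00225, and adjusted p = 0.752 with an estimated correlation), and 39 of the 43 were lower in both sorts. The ribosomal shift was -0.12 after quantile normalization (adjusted p = 0.0822), -0.15 without ACKR4-negative replicate 2 (adjusted p = 0.163) and 0.05 without ACKR4-positive replicate 1 (adjusted p = 0.804). With fry the calls of cell cycle (adjusted p = 0.278), ribosomal (adjusted p = 0.613), erythroid (adjusted p = 0.124), fibroblastic reticular (adjusted p = 0.369), basement membrane (adjusted p = 0.0693) and pan-endothelial genes (adjusted p = 0.0528) were lost. With ranks those of Notch, VEGF and lipid genes were lost (adjusted p = 0.0825 to 0.167), and with the stricter filter those of erythroid (adjusted p = 0.115), fibroblastic reticular (adjusted p = 0.0516) and cell junction genes (adjusted p = 0.101).

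**Figure D4:**
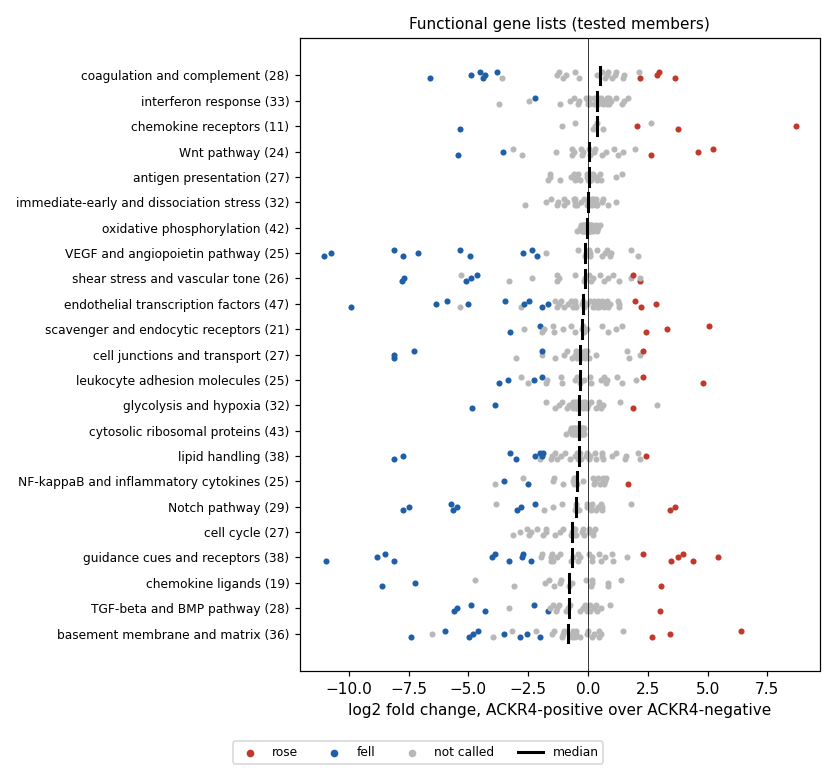
Log2 fold change of each tested member of the 23 functional lists, ACKR4-positive over ACKR4-negative, with risen members in red, fallen members in blue, members not called in grey and the list median as a black bar. Ribosomal protein genes lie close together around -0.38, while VEGF and guidance genes spread from below -10 upward.

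Other functional lists were not called with the reported settings. Wnt pathway genes (adjusted p = 0.976) held 3 rises among 24 members, Wnt9b at 5.22 ± 0.43, Wnt2 and Fzd9 at 2.62, and 2 falls, the Wnt antagonist gene Dkk2 at -5.44 ± 0.68 (at least 11.6-fold) and Tcf7 at -3.57 ± 0.35, with 4 risen and 5 fallen adjusted over the list alone. Scavenger and endocytic receptor genes (adjusted p = 0.478) held rises of Clec4g, Scarf2 at 3.29 ± 0.30 and Vldlr and falls of Scarb1 and Cd36, with 4 risen and 5 fallen adjusted over the list alone. Leukocyte adhesion genes (adjusted p = 0.391) held rises of Alcam at 4.79 ± 0.54 and Jam2 and 4 falls, those of Cd44 at -3.70 ± 0.33, Selp (also in the platelet list), Cd34 and Esam, with 5 risen and 5 fallen adjusted over the list alone. Alcam lost its call without ACKR4-positive replicate 1 (adjusted p = 0.0511) and Jam2 without any 1 of the 4 arrays (adjusted p = 0.0566 to 0.115). Scarf2 and Tcf7 lost theirs without ACKR4-negative replicate 1 (adjusted p = 0.0570 and 0.0543), Dkk2 without ACKR4-positive replicate 1 (adjusted p = 0.0670) and with normexp (-1.96, adjusted p = 0.124), and Cd36 without any 1 of the 4 arrays (adjusted p = 0.0706 to 0.195) and with quantile normalization (adjusted p = 0.130).

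The lists of this paragraph were called with fry (adjusted p = 0.0124 to 0.0237), not with an estimated correlation (adjusted p = 0.416 to 0.858), and in 5 (shear stress), 6 (transcription factors), 1 (coagulation) and 6 (glycolysis) of 19 alternatives. Shear stress and vascular tone genes (adjusted p = 0.0665) held 5 falls among 26 members, among them the endothelin receptor gene Ednrb at -7.77 ± 0.30 and the guanylate cyclase gene Gucy1b1 at -7.70 ± 0.36 (at least 57.3-fold), and 2 rises, Thbd at 2.16 and Trpv4 at 1.90, with 10 fallen and 4 risen adjusted over the list alone. Endothelial transcription factor genes (adjusted p = 0.0596) held 9 falls among 47 members, among them Tbx3 at -6.35 ± 0.35 and Foxf1 at -5.03 ± 0.43, and 3 rises, among them those of Meox1 and Nr2f2, with 11 fallen and 3 risen adjusted over the list alone. Coagulation and complement genes (adjusted p = 0.853) held 6 falls, among them that of C1qtnf1 at -4.37 ± 0.32, and 4 rises among 28 members, with 10 fallen and 7 risen adjusted over the list alone. Glycolysis and hypoxia genes (adjusted p = 0.0596) held falls of the lactate transporter gene Slc16a3 at -4.85 ± 0.27 and the glucose transporter gene Slc2a3 at -3.88 ± 0.40 and a rise of Ndrg1 at 1.89 ± 0.28, with 4 fallen and 2 risen adjusted over the list alone. Slc2a3 lost its call without ACKR4-positive replicate 1 (adjusted p = 0.0511) and Ndrg1 without any 1 of the 4 arrays (adjusted p = 0.0995 to 0.216). Adm was called with the replicate block (adjusted p = 0.0182).

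NF-kappaB and cytokine genes (adjusted p = 0.162) held falls of Ltb at -3.49 ± 0.54 and Il7 at -2.53 ± 0.32 (at least 1.69-fold) and a rise of Traf1 at 1.69 ± 0.27, with 4 fallen and 1 risen adjusted over the list alone. Interferon response genes (adjusted p = 0.133) held 1 fall among 33 members, that of Rsad2 at -2.21 ± 0.34, and 0 adjusted over the list alone. The replicate block called Il6 of the first list (adjusted p = 0.0125) and Isg20, Oas1a and Iigp1 of the second (adjusted p = 0.00941 to 0.0249). Normexp called Isg20 and Oas1a (adjusted p = 0.0454 and 0.0365). Ltb and Il7 lost their calls in all fits without 1 array but that without ACKR4-positive replicate 2 (adjusted p up to 0.115 and 0.112), Il7 also with normexp (-0.44, adjusted p = 0.680), and Traf1 and Rsad2 in all 4 (adjusted p up to 0.265 and 0.186). Traf1 and Rsad2 also lost their calls without a filter (adjusted p = 0.0685 and 0.0502). The stricter filter ended the calls of Traf1, Rsad2 and Ltb (adjusted p = 0.05005 to 0.0529). Antigen presentation (adjusted p = 0.976, 27 members), immediate-early and dissociation stress (adjusted p = 0.339, 32 members) and oxidative phosphorylation (adjusted p = 0.940, 42 members) held 0 called genes each, also adjusted over the list alone. The replicate block called Cd1d1 of the first (adjusted p = 0.0194) and Hspb1, Dusp2 and Ier5 of the second (adjusted p = 0.00720 to 0.0320). The immediate-early median was -0.55 without ACKR4-positive replicate 1 and -0.35 without ACKR4-negative replicate 2. It was 0.34 without ACKR4-positive replicate 2 and 0.20 without ACKR4-negative replicate 1. For oxidative phosphorylation it was 0.41 without ACKR4-positive replicate 1 and -0.46 without ACKR4-positive replicate 2. In these unpaired fits the groups no longer hold both sorts alike, so a difference between sorts enters the group difference. From sort 1 to sort 2 the median change of immediate-early genes was -0.50 in ACKR4-negative and -0.96 in ACKR4-positive cells. For oxidative phosphorylation it was 0.53 and 0.87. The median, mean and test direction differed in sign for granulocyte, lymphocyte, Wnt, antigen presentation and coagulation genes. Of 100 called named genes, 61 kept their call in all 4 fits that left out 1 array.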

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

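Alternatives without Ackr4 and the megakaryocyte members in other lists, and with usual gene names alone (878 genes called), were chosen after seeing the data. The 976 called genes became 441 when limited to probes well above background on all 4 arrays (15705 genes tested, 441 of them among the 976) and 2656 with the replicate block. Under the other settings the count was 778 to 1455, and without 1 array it was 387 to 892, where the lone array of a group was taken to vary like the pair of the other group. Genes 2-fold apart in both sorts, 2180 as reported, numbered 1405 with normexp and 1417 with the stricter filter. The correlation of the sorts, 0.817 as reported, was 0.810 with normexp, 0.691 without a filter, 0.762 with the stricter filter and 0.811 on the authors' values. Lists called, 18 as reported, numbered 0 with an estimated correlation, 12 to 20 in the other settings and 16 to 21 without 1 array. Ackr4 stayed called in every setting that tested it, with log2 fold changes of 4.81 (normexp) to 8.76 (median centring) and of 7.31 to 10.07 without 1 array. The stricter filter left it untested. Under that filter the VEGF list median was 0.068 and Gja5, read from another probe, was 0.17. Without 1 array, list medians ran from -4.14 to 0.35 for erythroid genes, -0.84 to 0.051 for ribosomal genes and -0.46 to 0.41 for oxidative phosphorylation. Of 1524 comparisons of 143 other named genes with an alternative, 1462 kept direction and call, 31 lost the call, 29 gained it, 1 reversed and 1 moved. Without 1 array, 455 of 572 were kept, 96 lost the call, 13 gained it and 8 moved. For lists, 468 of 555 comparisons were kept, and 110 of 148 without 1 array. Median centring put the median change of all genes at 0.11, against 0.04 as reported. The causes were not tested, apart from fewer genes or arrays by construction. Without 1 array the groups no longer hold both sorts alike, so differences between sorts enter the values without 1 array. The 2-fold counts and the correlation need both sorts and have no value without 1 array. The slide block was not run. Signal near background limits the folds of 335 called genes, which were dim in 1 group.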

Other observations

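All tests of this section were chosen after results were seen, and the tests with second marker lists use only members whose values had not been read when the lists were written. The genes of this paragraph were also chosen after their values were seen, as picks from the 30 that follow the 10 largest in each direction. Among genes after the 10 largest rises were Wnt9b at 5.22, Trpm6, a magnesium channel gene, at 4.99, Lbp, the lipopolysaccharide-binding protein gene, at 4.93, Ret, a receptor tyrosine kinase gene, at 4.59, and Anpep, an aminopeptidase gene, at 4.40. Trpm6 and Ret were well above background on neither ACKR4-negative array, and their rises were at least 12.5-fold and 7.25-fold. Among the next falls were Nfe2, a transcription factor of megakaryocytes, at -8.31, Igfbp3 at -7.56 (at least 89.9-fold), F13a1 at -7.50 (at least 59.3-fold) and Dpp4 at -7.35 (at least 66.3-fold).

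Sort 2 differed from sort 1 in the same way in both groups for a set of genes. Of 17362 tested genes, 213 were at least 4-fold higher in sort 2 in both groups and 21 were lower. S100a9 and Cd300lf, genes of myeloid cells, were higher in sort 2 by 4.63 and 5.13 in ACKR4-negative and by 6.25 and 4.62 in ACKR4-positive cells. The heat shock gene Hspa1a was lower in sort 2, with changes of -3.96 and -4.19. On ACKR4-positive replicate 1, 140 genes lay at least 4-fold above each of the other 3 arrays, against 19 to 32 on the other arrays.

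Of 18 tested megakaryocyte and platelet genes, 15 were called higher in ACKR4-negative cells, and 5 of the 18 are in other lists, among them Selp, Mmrn1 and Alox12, which endothelial cells also express. A lower share of endothelial cells with more of every other type alike was argued against for leukocytes only. The CD45 depletion and gate act on leukocytes in both groups, so their values do not speak for cells without CD45. The upper quartile of the megakaryocyte list, -3.58, lay below the lower quartile of 33 leukocyte members, -1.54. It also lay below that of 17 fibroblastic reticular members, -1.74. The CD31 gate should leave these cells out of both groups, so their values do not decide the question for cells without CD45. Mural genes (median -3.72) fell as well. Erythroid genes had a median of -1.97, but it was -4.53 in sort 1 and 0.60 in sort 2. RNA of megakaryocytes or platelets, which carry CD31, cannot be told apart from expression by ACKR4-negative endothelium, which was not tested. Falls of genes in other lists could hold such RNA as well, which was also not tested. Of a second list of 16 members (median -4.01, 14 lower in both sorts), 9 had been read as falls before it was written, and the other 7, which this split biases towards small changes, had a median of -1.65 with 5 lower in both sorts (71.4%, below the 75% asked for).

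Of 15 tested mural genes, 4 were called higher in ACKR4-negative cells and 14 were higher in both sorts, and with an estimated correlation the list was not called (adjusted p = 0.402). Pericytes and smooth muscle cells lack CD31, so the gate should leave them out. Of the list's 17 members, 2 are in other lists. RNA of pericytes or smooth muscle cells cannot be told apart from expression of these genes by ACKR4-negative endothelium, which was not tested. Of a second list of 13 tested members (median -3.26, 10 lower in both sorts, 76.9%), 2 had been read as falls before, and the other 11, which this split biases towards small changes, had a median of -3.06 with 8 lower in both sorts (72.7%, below the 75% asked for).

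The 213 genes were chosen as higher in sort 2 in both groups, and the array with the weak spike-in is in 1 group. The choice of genes therefore allowed no test of that array as the cause. Across all tested genes the sort differences correlated between the groups at 0.605, a value known before the question was asked. Signal on unannotated transcribed or genomic sequence may account for part of the rise in sort 2. Of the 213, 126 (59.2%) had predicted or clone-type names, against 24.8% of tested genes (Fisher's exact test, 2-sided, p = 1.15e-26, with genes that are not independent). The excess was not particular to sort 2. Among genes high on 1 array alone, such names made up 41.4% on ACKR4-positive replicate 1, in sort 1, and 36.8% on ACKR4-positive replicate 2. On ACKR4-negative replicates 1 and 2 they made up 11.1% and 18.8%. Leukocytes carried over in sort 2 cannot be told apart from other causes, though the CD45 depletion and gate should remove them, since the sort difference of 33 leukocyte members had medians of 0.79 and 0.95, below the log2 of 2 asked for, and an upper quartile of 1.97 in ACKR4-negative cells (bootstrap 95% range 1.05 to 2.86) and 3.06 in ACKR4-positive cells (1.22 to 4.64), where a quartile below 2 beyond its spread would count against them. This test first counted against leukocytes, a count of members then replaced it and was withdrawn, and the spread was added after the value was seen. By the withdrawn count, 7 of 33 leukocyte members (21.2%) were among the 213, against 1.23% of tested genes (Fisher's exact test, 2-sided, p = 1.23e-07). That share goes with leukocyte RNA in sort 2, while the medians fall short of the log2 of 2 asked for, so this cause stays open. No biological explanation was tested, because the labels give none for the sorts.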
